A study of Drosophila melanogaster with 15 samples.

How the data were processed

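RNA sequencing values of 15 libraries were analysed, 3 per group in 5 groups. Per the labels, each library pooled tissue of 25 to 30 eye discs of third-instar Drosophila melanogaster larvae, of which the part with GFP (the GMR domain) was kept after surgery. RNA was extracted with RNeasy columns and libraries were made from polyadenylated RNA with a TruSeq kit; whether strand was kept is not stated. The groups were the eGFP control, Monosiga Yap, Monosiga Yap joined to the TEAD-binding domain of a human protein (Monosiga Yap-TBD), Drosophila Yki S168A and Trichoplax Yap S81A. All expressed their construct under GMR-Gal4.

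Per the submitters' processing notes, CASAVA 1.7.0, TopHat 1.0.14, Cufflinks (version not given) and Cuffdiff 1.0.2 were used with genome build dm3. The role and order of these tools, the annotation and the filters are not stated. The deposited FPKM values (fragments scaled to transcript length and to library size by the authors) cover 14671 genes, and further scaling between libraries is not stated. A second deposited table gives, for 14672 genes, the natural log ratios of each construct over the control that the authors computed, limited to -6 and 6. The deposited p-value of each gene and comparison was computed by the authors. The adjusted values deposited beside it exceed 1 in places, so they were treated as a score that the authors derived from p. The deposited table also holds a mean level on the log2 scale, limited below at -6 by the authors, which was not used here. Reads and read counts were not used here, so no count-based test was run.

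The depth was estimated from the deposited FPKM values. Relative depth came from the steps between low values of the libraries, and the absolute depth from the whole multiples of the smallest value in 696 genes, with a length correction of 204 bases. The estimates were 14, 15.8 and 14.1 M fragments for control replicates 1, 2 and 3, 17.2, 16.1 and 16.3 M fragments for Monosiga Yap, and 16.7, 12.1 and 13.8 M fragments for Monosiga Yap-TBD. They were 14, 15.2 and 20.7 M fragments for Yki S168A and 13.9, 14.7 and 17.3 M fragments for Trichoplax Yap S81A, with a mean of 15.5. At 12.1 M fragments, an FPKM of 1 in a transcript of 2000 bases rests on about 24.0 fragments. Correlations between libraries of a group were 0.931 to 0.966 and no library was a copy of another. With 3 libraries per group no outlier test was run, and all libraries were kept.

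Gene symbols were taken from the deposited table of comparisons for 13520 genes and from a gene name table for 914 more, and 237 genes had none. Older symbols are used as deposited, with mus209 for PCNA, ial for aurB, E2f for E2f1, CG33967 for kibra and CG16857 for bdl. Of the genes, 1425 were listed at 0 in every library.

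Values were taken to log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 3 libraries were tested (9213 genes). A linear model with all 5 groups was fitted in limma 3.58.1 (R 4.3.3), with a trend of variance on level and robust empirical Bayes moderation (10 residual and a median of 3.7 prior degrees of freedom). The 10 contrasts between groups were tested on both sides, p was adjusted over genes by Benjamini-Hochberg, and genes with limma adjusted p under 0.05 were called. The median standard error of a log2 fold change was 0.193. Fold changes in the text are ratios of mean FPKM, and errors are standard deviations of 3 libraries unless given as SE. The other computations used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

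The 21 gene lists were written from general knowledge of fly genes, and 529 of 534 entries matched a gene. They cover Yki targets, Hippo pathway components, DNA replication and G1/S, mitosis and G2/M, ribosome biogenesis, retinal determination and anterior progenitors, photoreceptor specification, neuronal differentiation, cone and pigment cells, Notch targets, apoptosis, JNK and tissue stress, heat shock, immune peptides, hemocyte markers, fat body markers, glia markers, muscle markers, antennal and head capsule markers, optic lobe and brain markers, and dosage and sex markers. Lists with at least 5 tested members were compared with the other genes by camera of limma with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Members were also counted after adjusting p over the list alone. Some genes stand on more than 1 list.

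The genes named were set by a rule. For the 4 comparisons with the control and for Monosiga Yap-TBD against Monosiga Yap and Trichoplax Yap S81A against Yki S168A, it named yki, th, ex, CycE, fj, kibra, Mer, dally, wg, vn, elav, sens, ato, hth and ey. It added the 6 called genes with the largest rise and the 6 with the largest fall whose libraries did not overlap between groups, with a mean FPKM of at least 5 in the higher group and a symbol other than a CG or CR number. Of each list it added up to 4 called members per direction with the smallest adjusted p. For length the text leaves out part of the genes that the rule named. This choice was made after the values were seen: outside the fixed names, genes whose call held under all alternatives were preferred. The rule does not cover the other 4 contrasts.

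The groups, contrasts, tests, lists, naming rule and first set of alternatives were chosen before the data were examined. These alternatives were pseudocounts of 0.1 and 5, no filter or a filter at an FPKM of 5, quantile normalization, centring of each library on its median, a replicate block, only the groups compared in the fit, array weights, a minimum change of 2-fold beside the adjusted p, the estimated inter-gene correlation, and leaving out each library in turn. Chosen after seeing the data were the main axis of deviations from the group means as a covariate, the roX level as a covariate, the fit without the 2 libraries of lowest roX level (Trichoplax Yap S81A replicate 2 and Monosiga Yap replicate 3), and the fit without the 4 libraries lowest on that axis (Monosiga Yap replicate 2, Yki S168A replicate 1, Monosiga Yap-TBD replicate 3 and Trichoplax Yap S81A replicate 1).

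Overlaps between comparisons with the control were set beside the product of the shares called and beside 100 simulations of unchanged groups that share the same control values. The calls were also tested on simulated data, in which 200 of 9213 genes were changed in the construct libraries. In the runs for Monosiga Yap, Monosiga Yap-TBD, Yki S168A and Trichoplax Yap S81A, changes of 2-fold were called in 46.3%, 67.2%, 52.2% and 76.1% of cases. Changes of 1.5-fold were called in 9%, 19.4%, 19.4% and 23.9%, and 6, 9, 5 and 8 unchanged genes were called. All runs used the same gene means, spread and number of changed genes, so their percentages differ by random draw and not by construct. Adjusted p depends on how many genes change. The percentages therefore do not give the share of changes found in the real comparisons, where that number differs.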

Results

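Messenger RNA was sequenced from the differentiating part of third-instar eye imaginal discs of Drosophila melanogaster, the larval tissue from which the adult eye forms. GMR-Gal4 drove each construct in the cells behind the morphogenetic furrow, and the GFP-positive domain was isolated surgically from 25 to 30 discs per library. There were 5 groups of 3 libraries: control discs that expressed only eGFP, Yap of the choanoflagellate Monosiga, the same protein joined to the TEAD-binding domain of a human protein (Monosiga Yap-TBD), Drosophila Yki with the S168A substitution, and Yap of the placozoan Trichoplax with the S81A substitution. Yki and Yap are the transcriptional coactivators that the Hippo pathway inhibits, and they act through TEAD-family proteins such as Scalloped. Per the labels, control eyes were normal, Monosiga Yap gave differentiation defects alone, Monosiga Yap-TBD and Trichoplax Yap S81A added strong ectopic proliferation, and Yki S168A added a middle degree of it.

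The depth, estimated from the values, lay between 12.1 M fragments in Monosiga Yap-TBD replicate 2 and 20.7 M fragments in Yki S168A replicate 3. At the lowest depth, an FPKM (fragments scaled to transcript length and library size) of 1 in a transcript of 2000 bases corresponds to about 24.0 fragments. Per library, 8194 to 9104 genes reached an FPKM of 1, and 9213 genes were tested. Among the genes named, ex, elav, Ts, Mcm10, sub, thr, cher, ru, neur, Obp44a, dan, so, repo, pip, y, RhoGEF4 and CG10051 overlap a gene on the other strand. The genes dally, hh, svp, Surf6, CG11029 and CG14681 overlap one on the same strand, and B4, CG32816 and CG32521 overlap genes on both. The labels do not state that strand was used, so the reads of such partners cannot be told apart.

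The level of yki itself, in the gene at 2R 19953498 to 19956008 (dm3), separated the Drosophila construct from the rest. It stood at 85.1 ± 4.57 FPKM in the control group (SD, n = 3), and at 695.5, 706.2 and 408.3 FPKM in the 3 Yki S168A libraries. Their mean was 7.09-fold higher (limma adjusted p = 3.33e-07). The other constructs carry foreign coding sequence, and yki was 79.8 ± 8.33 FPKM with Monosiga Yap (limma adjusted p = 1), 71.6 ± 5.45 with Monosiga Yap-TBD (adjusted p = 0.331) and 75.3 ± 3.32 with Trichoplax Yap S81A (adjusted p = 0.586).

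The comparison of Monosiga Yap with the control asks what the choanoflagellate protein does in fly tissue without an added TEAD-binding domain. Few genes were called. Rh5, a rhodopsin gene, rose from 0.89 ± 0.44 to 7.22 ± 1.07 FPKM (8.14-fold, limma adjusted p = 0.000207), and Cda5, which encodes a chitin deacetylase, rose from 1.44 to 9.16 FPKM (6.36-fold, adjusted p = 0.00221). Gld, the glucose dehydrogenase gene, rose 3.12-fold (limma adjusted p = 0.00589). Tektin-C, of a family of proteins of ciliary microtubules, fell from 138.4 ± 8.90 to 60.2 ± 8.59 FPKM (limma adjusted p = 0.0008). Of the 30 calls, 16 were called in the same direction with all 4 constructs, Rh5 and Tektin-C among them. Such changes are not particular to Monosiga Yap.

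Of the genes that respond to Yki in flies, expanded (ex; 2L 431253 to 448701), an upstream component of the Hippo pathway that Yki also induces, was called alone. It rose from 54.6 ± 2.13 to 97.5 ± 14.2 FPKM (1.79-fold, limma adjusted p = 0.0268). That call ended when any 1 of control replicates 1, 2 and 3 or Monosiga Yap replicates 1, 2 and 3 was left out. The limma adjusted p then lay between 0.0584 and 0.152, and between 0.00328 and 0.152 over all alternatives. CycE, dally, wg and fj stood at 12.2, 72.8, 4.16 and 41.2 FPKM (limma adjusted p = 1 for each). The gene vn, which encodes a ligand of the EGF receptor, stood at 2.41 against 1.27 FPKM (limma adjusted p = 0.759). The pan-neuronal gene elav was 48.2 ± 5.14 FPKM against 49.3 ± 8.58 in the control (limma adjusted p = 1).

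Among 15 tested Yki targets, 1 rose (2 adjusted over the list alone). Camera of limma gave adjusted p = 0.006, and adjusted p = 0.85 with an estimated correlation. Among 40 genes of neuronal differentiation, 1 rose (1 adjusted over the list alone), namely Rh5, with limma camera adjusted p = 0.00411 and adjusted p = 0.85 with an estimated correlation. In the other 19 lists limma called 0 members, and 1 cone and pigment cell gene when adjusted over the list alone. The median and mean differed in sign for fat body markers (0.02 and -0.02), and DNA replication genes had a median of -0.03 with an upward test.

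In all, 30 of 9213 genes were called, 21 higher and 9 lower, while 455 had an unadjusted limma p under 0.05. The count was 17 without control replicate 1, 17 without control replicate 2, and 16, 18 and 17 without Monosiga Yap replicate 1, 2 or 3. It was 17 without the libraries of lowest roX level, 16 with only the groups compared in the fit, 58 with the within-group axis as a covariate and 79 with array weights. The call of Gld ended with only the groups compared in the fit (limma adjusted p = 0.0809, with a range of 0.00075 to 0.0809 over its alternatives).

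**Figure D1:**
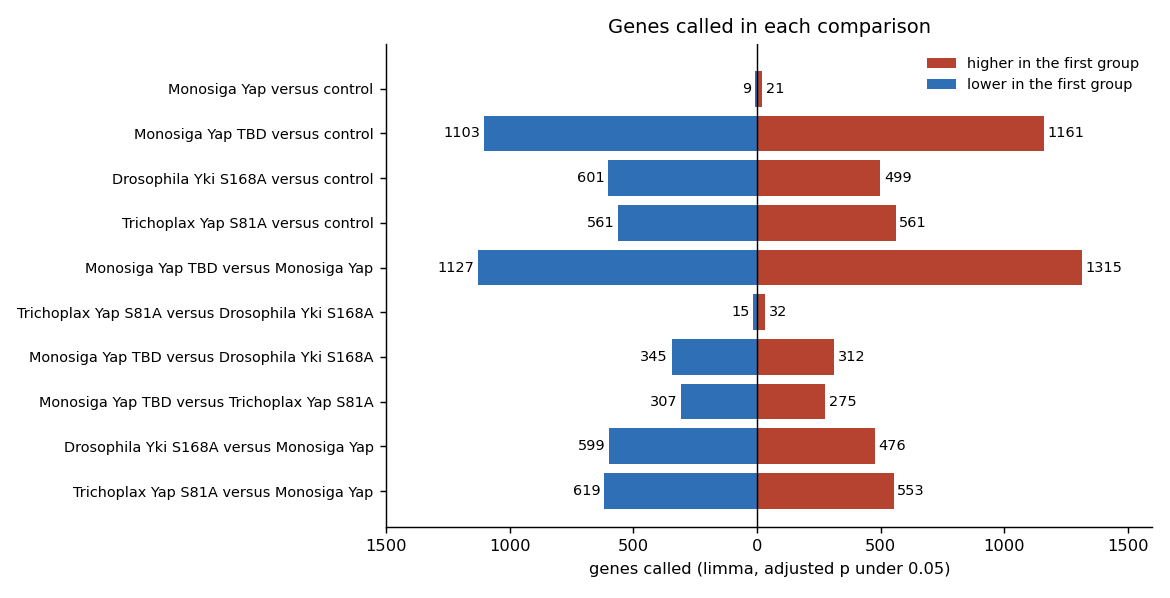
Number of genes called at an adjusted p under 0.05 in each comparison (bars; genes higher and lower in the first-named group, of 9213 tested). Monosiga Yap against control has 30 calls and Monosiga Yap-TBD against control 2264.

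Monosiga Yap-TBD against the control shows the same protein with a domain that binds TEAD proteins. Several genes known to respond to Yki and many replication genes rose, and many genes of photoreceptors and cone cells fell. Expression of ex rose to 309 ± 36.2 FPKM (SD, n = 3; 5.66-fold, limma adjusted p = 5.54e-08). CycE, the cyclin gene of S-phase entry, rose from 12.3 ± 0.81 to 36.5 ± 2.37 FPKM (2.98-fold, limma adjusted p = 3.91e-05), and vn to 18.5 ± 1.71 FPKM (14.5-fold, adjusted p = 2.51e-07). The receptor tyrosine kinase gene sevenless (sev), which the R7 photoreceptor needs, fell to 9.38 ± 0.87 FPKM, 0.0816 of the control level (limma adjusted p = 9.88e-08), and elav fell from 49.3 ± 8.58 to 14.95 ± 1.98 FPKM (adjusted p = 1.39e-05).

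Among the Yki targets, 10 of 15 rose (11 adjusted over the list alone; limma camera adjusted p = 2.57e-08, adjusted p = 0.0873 with an estimated correlation). They include kibra, an upstream Hippo component listed as CG33967 (3.63-fold, limma adjusted p = 5.08e-06), dally, which encodes a glypican (2.76-fold, adjusted p = 8.54e-06), and fj, which encodes a Golgi kinase (2.09-fold, adjusted p = 2.33e-05). The Wnt gene wg rose from 3.92 ± 1.40 to 12.1 ± 4.67 FPKM (limma adjusted p = 0.0123), a call that ended without control replicate 3 or Monosiga Yap-TBD replicate 2. Its limma adjusted p ranged from 0.00955 to 0.0637 over the single libraries left out and from 0.00306 to 0.0637 over all alternatives. The caspase inhibitor gene th (Diap1) stood at 326 against 302 FPKM (limma adjusted p = 0.322), and Mer at 27.1 against 23.3 (adjusted p = 0.175). Of 25 Hippo pathway components, 7 rose and 4 fell, also when adjusted over the list alone (limma camera adjusted p = 0.455). The kinase gene wts rose 2.84-fold (limma adjusted p = 5.37e-06) and the atypical cadherin gene ft 2.02-fold (adjusted p = 3.07e-05), while lft fell to 0.561 of the control (adjusted p = 0.000952).

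Of 48 DNA replication genes, 37 rose (40 adjusted over the list alone). Camera of limma gave adjusted p = 6.95e-18, and adjusted p = 0.293 with an estimated correlation. The PCNA gene mus209 rose from 133 ± 7.99 to 326 ± 19.2 FPKM (limma adjusted p = 4.05e-06), and RPA2 and Mcm5, of the replication machinery, rose 2.74-fold and 2.29-fold. Of 54 mitosis genes, 21 rose and 1 fell (28 and 1 adjusted over the list alone; limma camera adjusted p = 7.25e-07, adjusted p = 0.382 with an estimated correlation). The kinesin gene sub rose 2.40-fold (limma adjusted p = 0.00012), and the centromeric histone gene cid rose from 1.13 to 5.98 FPKM (adjusted p = 0.000161). The single member that fell was stg, the phosphatase gene that starts mitosis, from 87.6 to 57.1 FPKM (limma adjusted p = 0.00639). Of 35 ribosome biogenesis genes, 23 rose (26 rose and 2 fell adjusted over the list alone; limma camera adjusted p = 2.57e-08, adjusted p = 0.317 with an estimated correlation). Surf6 rose 2.28-fold (limma adjusted p = 0.0012).

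Of 36 genes of photoreceptor specification, 21 fell and 4 rose (23 and 6 adjusted over the list alone; limma camera adjusted p = 2.74e-07, adjusted p = 0.0873 with an estimated correlation). The zinc finger genes salr and salm fell to 1.67 and 0.69 FPKM from 27.6 and 12.5 (limma adjusted p = 1.2e-07 and 5.87e-07). The gene ru, which encodes a protease that activates EGF ligands, fell from 141 to 23.5 FPKM (limma adjusted p = 1.92e-06). Of the members that rose, dpp, a BMP ligand gene, went from 6.62 ± 0.90 to 28.1 ± 1.20 FPKM (limma adjusted p = 8.01e-07). Among 40 neuronal genes, 19 fell and 4 rose (21 and 5 adjusted over the list alone; limma camera adjusted p = 1.09e-06, adjusted p = 0.317 with an estimated correlation). Of these, inaC, an eye protein kinase C gene, fell from 43.6 to 3.99 FPKM and chp, which encodes the photoreceptor adhesion protein chaoptin, from 36.4 to 3.31 FPKM (limma adjusted p = 2.24e-08 and 1.64e-07). Rh5 rose here also, to 6.73 FPKM (limma adjusted p = 8.72e-06). Of 16 cone and pigment cell genes, 9 fell and 2 rose (9 and 3 adjusted over the list alone; limma camera adjusted p = 0.00308, adjusted p = 0.317 with an estimated correlation). The Pax2 gene of cone cells, sv, fell from 15.6 to 0.66 FPKM (limma adjusted p = 4.8e-08). Of 13 retinal determination genes, 4 fell, also when adjusted over the list alone (limma camera adjusted p = 0.0405, adjusted p = 0.382 with an estimated correlation). They were dan, danr, eya and so, of which eya went from 155 to 81.4 FPKM (limma adjusted p = 0.00101). Neither hth (137 against 106 FPKM, limma adjusted p = 0.227) nor ey or ato passed the test (adjusted p = 0.563 and 0.111). The proneural gene sens, at 4.50 against 7.67 FPKM (limma adjusted p = 0.0195), lost its call without control replicate 2 or 3 or Monosiga Yap-TBD replicate 1 or 2. Leaving out single libraries moved its limma adjusted p from 0.0183 to 0.0814, and all alternatives from 0.000984 to 0.0814.

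Among the largest rises, Cpr97Eb, a cuticle protein gene, went from 1.01 ± 0.60 to 270.3 ± 19.3 FPKM (limma adjusted p = 1.1e-08), and Cpr12A and TwdlE, also cuticle protein genes, reached 42.8 and 665 FPKM from 0.31 and 47.7. Of 36 cuticle protein genes, a group chosen after the values were seen, 6 rose and 5 fell by limma (median log2 fold change -0.28). Ts, the thymidylate synthase gene, went from 0.09 to 44.8 FPKM, and Cyp18a1, whose enzyme inactivates ecdysteroids, from 0.26 to 21.7 FPKM (both limma adjusted p = 7.94e-09). For Ts, the authors' deposited log ratio in this comparison was 0. The small nuclear RNA gene snRNA:U12 went from 8.93 ± 3.48 to 171.65 ± 64.56 FPKM (19.2-fold, limma adjusted p = 1.12e-06). The libraries were made from polyadenylated RNA. Of 171 small RNA genes 4 rose and 2 fell by limma, with log2 fold changes from -3.42 to 5.53. Among the largest falls, ana, which encodes a secreted glial glycoprotein, went from 34.2 ± 11.2 to 0.60 ± 0.14 FPKM (limma adjusted p = 2.53e-08).

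Of 22 genes of JNK signalling and tissue stress, 3 rose and 3 fell (6 and 3 adjusted over the list alone; limma camera adjusted p = 0.15). The filamin gene cher rose from 29.4 to 201 FPKM (limma adjusted p = 5.54e-08), and egr, the TNF gene of the fly, fell from 32.4 to 9.43 FPKM (adjusted p = 1.84e-05). Of 15 heat shock genes, 7 fell (9 adjusted over the list alone; limma camera adjusted p = 0.00134, adjusted p = 0.317 with an estimated correlation). Hsp67Bc fell from 363 to 72.7 FPKM (limma adjusted p = 0.000111). Of 19 hemocyte markers, 5 fell, also when adjusted over the list alone (limma camera adjusted p = 0.000439, adjusted p = 0.317 with an estimated correlation). BM-40-SPARC, a basement membrane gene, fell from 84.9 to 24.4 FPKM (limma adjusted p = 1.12e-05). Of 16 Notch targets, 4 fell, also when adjusted over the list alone (limma camera adjusted p = 0.0639). Among them neur, a ubiquitin ligase gene of Notch signalling, fell from 38.6 to 13.4 FPKM (limma adjusted p = 2.1e-05).

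In the remaining lists camera made no call. Of 13 antennal and head capsule markers, 1 rose and 6 fell (2 and 6 adjusted over the list alone; limma camera adjusted p = 0.0605), and the falling members include dan, danr, so and lz, which also act in the eye. Of 16 apoptosis genes, 2 fell (2 adjusted over the list alone; limma camera adjusted p = 0.115). Of 15 fat body markers 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0834), with Obp44a from 448 to 64.6 FPKM (limma adjusted p = 8.05e-06). Glia markers gave 2 higher and 4 lower of 15, also when adjusted over the list alone (camera adjusted p = 0.455), repo among the lower (limma adjusted p = 0.00386). Muscle markers gave 2 higher and 4 lower of 17, also when adjusted over the list alone (limma camera adjusted p = 0.393). Optic lobe and brain markers gave 1 higher and 4 lower of 13, also when adjusted over the list alone (limma camera adjusted p = 0.15). The higher one was Gad1, the gene of GABA synthesis, at 3.93 against 0.05 FPKM (limma adjusted p = 4.37e-06). Immune peptides gave 1 higher of 17 (1 adjusted over the list alone; limma camera adjusted p = 0.997, with a median below 0 and a mean above it). Dosage and sex markers gave 1 higher and 1 lower of 10, also when adjusted over the list alone (limma camera adjusted p = 0.625).

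With Monosiga Yap-TBD, 2264 genes were called, 1161 higher and 1103 lower, and 871 of them (332 higher and 539 lower) changed at least 2-fold. Array weights gave 4014 calls and the within-group axis as a covariate 3458.

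**Figure D2:**
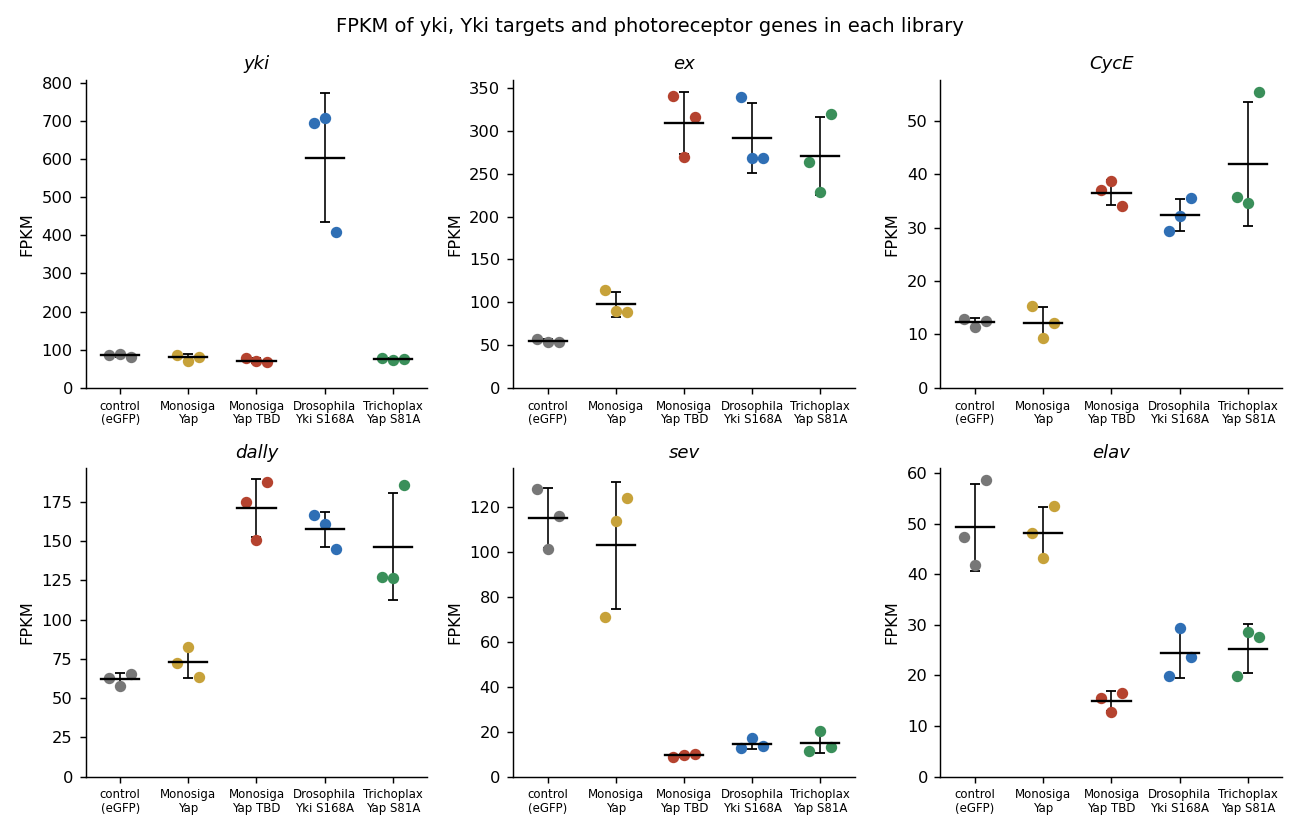
FPKM of yki, ex, CycE, dally, sev and elav in each of the 15 libraries (points), with the mean and SD of each group (bars and lines). The gene ex lies between 53.1 and 57.0 FPKM in the control libraries and sev between 8.49 and 20.3 with the 3 constructs that gave ectopic proliferation.

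Yki S168A against the control tests the fly protein with a substitution at a site through which the Hippo pathway restrains it. Several Yki targets and many replication genes rose, several photoreceptor genes fell, and wg and hth rose. Expression of ex rose to 292 ± 41.1 FPKM (SD, n = 3; 5.35-fold, limma adjusted p = 3.33e-07) and of wg from 3.92 ± 1.40 to 66.8 ± 26.9 FPKM (17.0-fold, adjusted p = 4.2e-05). The homeobox gene hth, of undifferentiated eye cells, rose from 106 ± 9.94 to 243 ± 36.3 FPKM (2.29-fold, limma adjusted p = 0.00161). The gene sev fell to 14.5 ± 2.12 FPKM (limma adjusted p = 2.8e-06), elav to 24.3 ± 4.78 (adjusted p = 0.00262) and ato, the proneural gene of the first photoreceptor, to 9.80 ± 0.40 from 25.1 ± 6.56 (adjusted p = 0.00847).

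Among the Yki targets, 10 of 15 rose (12 adjusted over the list alone; limma camera adjusted p = 1.34e-11, adjusted p = 0.051 with an estimated correlation). Among them CycE rose 2.64-fold, kibra 3.31-fold, dally 2.55-fold, vn 3.63-fold and th 1.47-fold (limma adjusted p = 0.000416, 6.16e-05, 9.13e-05, 0.00147 and 0.000354). Values of fj and Mer were 35.1 and 26.6 FPKM (limma adjusted p = 0.577 and 0.319). Hippo components gave 5 higher and 1 lower of 25, also when adjusted over the list alone (limma camera adjusted p = 0.233). The kinase gene wts stood at 42.9 against 17.8 FPKM and the cadherin gene ds at 85.1 against 42.6 FPKM (limma adjusted p = 0.000126 and 0.000887). Replication genes rose in 31 of 48 cases (35 adjusted over the list alone; limma camera adjusted p = 4.93e-22, adjusted p = 0.153 with an estimated correlation). The level of mus209 rose to 303 FPKM and that of RnrL, a ribonucleotide reductase gene, to 72.4 against 32.3 (limma adjusted p = 4.7e-05 and 0.000152). Mitosis genes rose in 21 of 54 cases (29 adjusted over the list alone; limma camera adjusted p = 2.81e-13, adjusted p = 0.362 with an estimated correlation). The kinesin gene pav rose 2.04-fold and the Aurora B gene ial 2.10-fold (limma adjusted p = 0.000808 and 0.00126). Ribosome biogenesis gave 5 higher of 35 (12 higher and 1 lower adjusted over the list alone; limma camera adjusted p = 1.92e-07, adjusted p = 0.385 with an estimated correlation). The first of these by p was Rrp1, which encodes a DNA repair endonuclease (limma adjusted p = 0.0013).

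Photoreceptor specification had 15 lower and 4 higher of 36 (18 and 5 adjusted over the list alone; limma camera adjusted p = 2.15e-05, adjusted p = 0.153 with an estimated correlation). Besides sev, salm and salr fell, to 1.83 and 5.24 FPKM (both limma adjusted p = 4.66e-05), while dpp rose 3.24-fold (adjusted p = 4.25e-05). The Hedgehog ligand gene hh rose from 21.8 ± 6.21 to 43.1 ± 3.38 FPKM (limma adjusted p = 0.00467). Neuronal genes had 13 lower and 3 higher of 40 (16 and 5 adjusted over the list alone; limma camera adjusted p = 0.000647, adjusted p = 0.385 with an estimated correlation). The level of inaC fell to 16.4 FPKM and that of Appl, the amyloid precursor gene, to 68.7 against 162 FPKM (limma adjusted p = 0.000123 and 0.00221). Notch targets gave 4 lower of 16 (6 adjusted over the list alone; limma camera adjusted p = 0.000751, adjusted p = 0.362 with an estimated correlation). The bHLH repressor gene HLHmdelta fell to 15.1 against 47.6 FPKM (limma adjusted p = 0.000815). Optic lobe and brain markers gave 1 lower of 13 (4 adjusted over the list alone; limma camera adjusted p = 0.0145, adjusted p = 0.153 with an estimated correlation). It was scrt, a zinc finger gene of neurons (limma adjusted p = 0.00324). Cone and pigment cell genes gave 3 higher and 3 lower of 16, also when adjusted over the list alone (limma camera adjusted p = 0.49). The lower ones include sv, at 1.32 FPKM (limma adjusted p = 7.7e-07), and the higher ones Notum, whose product inactivates Wnt ligands, at 27.8 ± 8.35 against 4.36 ± 0.96 FPKM (adjusted p = 0.00152). Retinal determination gave 2 higher and 1 lower of 13 (2 and 2 adjusted over the list alone; limma camera adjusted p = 0.627), hth among the higher. The call of sens, at 4.52 FPKM (limma adjusted p = 0.0326), ended without control replicate 2 or 3 or Yki S168A replicate 2 or 3. Its limma adjusted p ranged from 0.0128 to 0.133 over the single libraries left out and from 0.000716 to 0.133 over all alternatives.

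Of the remaining lists, heat shock gave 4 lower of 15 (4 adjusted over the list alone; limma camera adjusted p = 0.00749, adjusted p = 0.362 with an estimated correlation). Among them was Hsp67Bc, at 125 FPKM (limma adjusted p = 0.00562). Hemocyte markers gave 3 lower and 1 higher of 19 (5 and 1 adjusted over the list alone; limma camera adjusted p = 0.000647, adjusted p = 0.362 with an estimated correlation). The higher one, the extracellular matrix gene Ppn, rose from 92.7 ± 17.5 to 179 ± 21.3 FPKM (limma adjusted p = 0.00333). Antennal markers gave 2 higher and 1 lower of 13 (3 and 3 adjusted over the list alone; limma camera adjusted p = 0.667, with a median below 0 and a mean above it). Dll, the homeobox gene of distal appendages, rose to 7.70 ± 2.32 against 0.40 ± 0.13 FPKM (19.5-fold, limma adjusted p = 9.74e-05). JNK and stress genes gave 3 higher and 2 lower of 22, also when adjusted over the list alone (limma camera adjusted p = 0.964, with a median below 0 and a mean above it). Glia markers gave 1 higher and 3 lower of 15 (1 and 4 adjusted over the list alone; limma camera adjusted p = 0.593, with a median above 0 and a mean below it). The higher one was nkd, a feedback inhibitor of Wnt signalling (limma adjusted p = 0.00441). Muscle markers gave 2 higher and 2 lower of 17 (2 and 3 adjusted over the list alone; limma camera adjusted p = 0.0992). Apoptosis genes and fat body markers gave 2 lower of 16 and 2 lower of 15, also when adjusted over the list alone (both limma camera adjusted p = 0.189). Dosage and sex markers gave 1 lower of 10 (1 adjusted over the list alone; limma camera adjusted p = 0.49). Among 17 immune peptides limma called 0 (0 adjusted over the list alone; camera adjusted p = 0.233).

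Among the largest rises were those of wg, yki, Ts, to 33.0 FPKM, TwdlE, to 738, and Mcm10, a replication gene, from 0.20 to 10.6 FPKM. For Ts and Mcm10 the authors' deposited log ratio was 0 here. The receptor gene mthl8 was listed at 0 in the control libraries and at 5.64 ± 0.31 FPKM with Yki S168A (limma adjusted p = 3.33e-07). In total 1100 genes were called, 499 higher and 601 lower, 382 of them with at least a 2-fold change (117 higher and 265 lower). Without control replicate 2 the count was 723, with array weights 3033 and with the within-group axis as a covariate 1993.

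**Figure D3:**
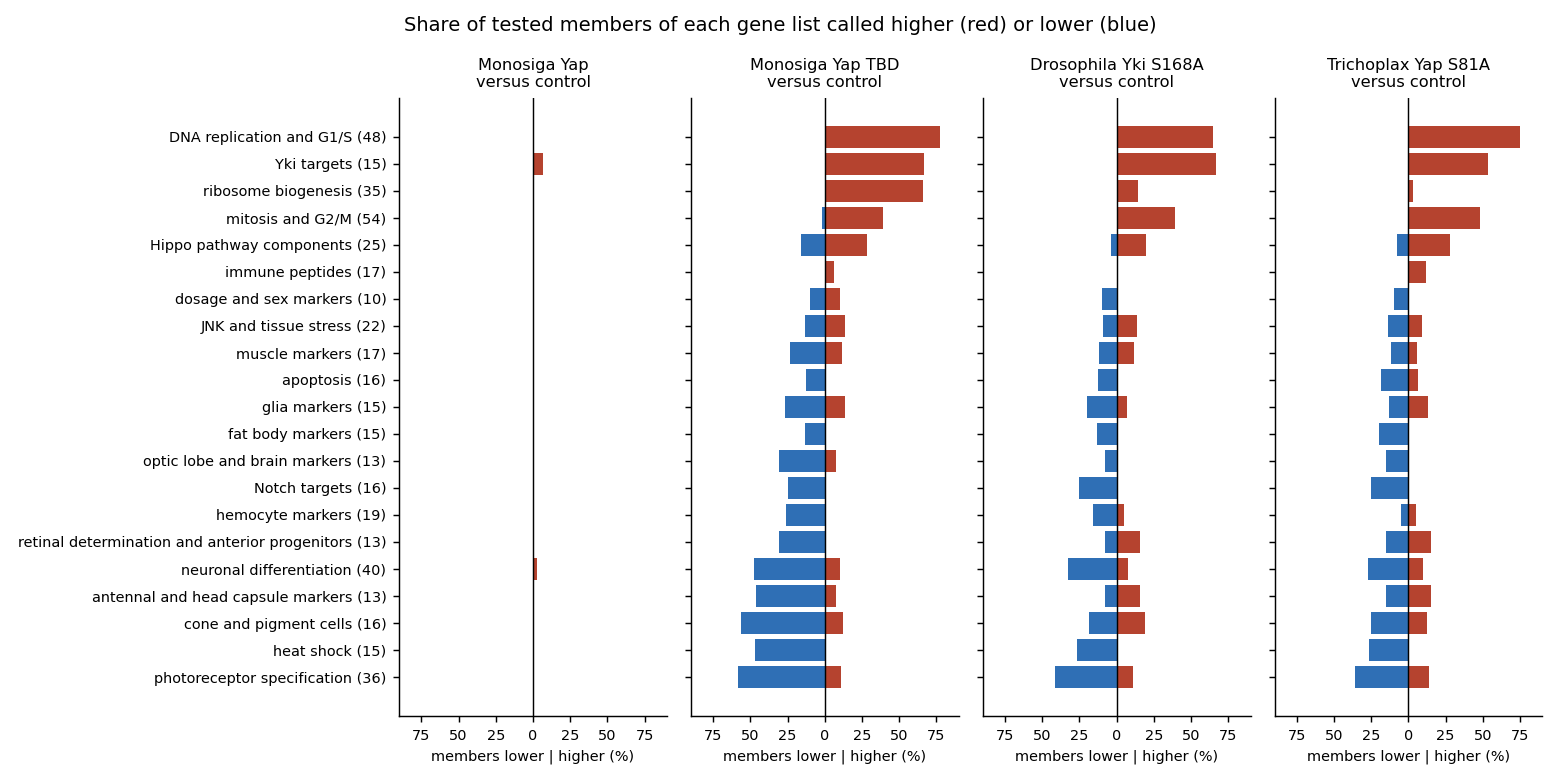
Share of the tested members of each gene list called higher (to the right) or lower (to the left) in the 4 comparisons with the control, in percent. DNA replication genes are called higher in 37, 31 and 36 of 48 cases with Monosiga Yap-TBD, Yki S168A and Trichoplax Yap S81A.

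Trichoplax Yap S81A against the control asks whether a placozoan protein acts in the same tissue. Expression of ex rose to 271 ± 46.0 FPKM (SD, n = 3; 4.96-fold, limma adjusted p = 4.32e-07), CycE to 41.9 ± 11.6 (3.42-fold, adjusted p = 5.35e-05) and wg to 121 ± 49.9 (30.8-fold, adjusted p = 3.04e-06). The gene sev fell to 14.97 ± 4.64 FPKM (limma adjusted p = 1.46e-06) and elav to 25.3 ± 4.82 (adjusted p = 0.00325). Among the genes that the naming rule covers, the largest rise was that of Ast-C, which encodes the neuropeptide allatostatin C. It went from 0.23 ± 0.40 to 177 ± 78.7 FPKM (limma adjusted p = 1.9e-08). The homeobox gene lbl rose from 0.13 to 29.0 FPKM (limma adjusted p = 4.44e-07), and TwdlE 47.8-fold to 2283.9 FPKM (adjusted p = 2.09e-07).

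Yki targets rose in 8 of 15 cases (12 adjusted over the list alone; limma camera adjusted p = 1.59e-11, adjusted p = 0.0522 with an estimated correlation). They include kibra (2.94-fold), dally (2.37-fold), vn (5.41-fold), th (1.43-fold) and E2f, an activator of S-phase genes (2.69-fold), with limma adjusted p = 8.88e-05, 0.000123, 0.000136, 0.000411 and 6.46e-05. The values of fj and Mer were 47.7 and 26.3 FPKM (limma adjusted p = 0.12 and 0.359). Hippo components gave 7 higher and 2 lower of 25, also when adjusted over the list alone (camera adjusted p = 0.297), with wts 2.37-fold and ds 2.03-fold higher (limma adjusted p = 0.000109 and 0.000583). Replication genes rose in 36 of 48 cases (41 adjusted over the list alone; limma camera adjusted p = 6.13e-26, adjusted p = 0.164 with an estimated correlation). The level of mus209 rose to 343 ± 32.4 FPKM (limma adjusted p = 7.46e-06). Mitosis genes rose in 26 of 54 cases (31 adjusted over the list alone; limma camera adjusted p = 2.16e-14, adjusted p = 0.291 with an estimated correlation). The kinesin gene sub rose 2.40-fold and the separase gene thr 2.72-fold (limma adjusted p = 0.000265 and 0.00087). Of 35 ribosome biogenesis genes, 1 rose (1 adjusted over the list alone; limma camera adjusted p = 0.00616, adjusted p = 0.643 with an estimated correlation). It was again Rrp1, which acts in DNA repair.

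Photoreceptor specification had 13 lower and 5 higher of 36 (16 and 5 adjusted over the list alone; limma camera adjusted p = 0.000163, adjusted p = 0.172 with an estimated correlation). Among the lower was salr, at 3.88 FPKM, and among the higher the bHLH gene h, at 73.7 ± 28.3 against 15.9 ± 2.63 FPKM, and hh, at 53.5 ± 7.46 FPKM (limma adjusted p = 6.34e-06, 0.000237 and 0.000607). Neuronal genes had 11 lower and 4 higher of 40 (14 and 4 adjusted over the list alone; limma camera adjusted p = 0.00186, adjusted p = 0.554 with an estimated correlation). Here inaC fell to 10.6 FPKM (limma adjusted p = 3.3e-06), whereas Rh5 and ninaC, the myosin III gene of photoreceptors, rose to 14.6 and 3.89 FPKM (adjusted p = 6.09e-07 and 4.62e-05). Notch targets gave 4 lower of 16 (7 adjusted over the list alone; limma camera adjusted p = 0.00119, adjusted p = 0.479 with an estimated correlation). Of these, HLHmdelta fell to 18.8 FPKM (limma adjusted p = 0.00219). Cone and pigment cell genes gave 2 higher and 4 lower of 16 (3 and 4 adjusted over the list alone; limma camera adjusted p = 0.285, with a median above 0 and a mean below it). Of these, sv fell to 0.79 FPKM and Notum rose to 40.9 ± 15.4 (limma adjusted p = 2.03e-07 and 0.000267). Retinal determination gave 2 higher and 2 lower of 13, also when adjusted over the list alone (limma camera adjusted p = 0.0721). Optix, a homeobox gene of eye progenitors, rose to 31.8 against 14.3 FPKM (limma adjusted p = 0.000874). The call of hth, at 174 ± 8.10 FPKM (limma adjusted p = 0.0326), ended when any of control replicates 1, 2 and 3 or Trichoplax Yap S81A replicates 1, 2 and 3 was left out. Its limma adjusted p was then between 0.051 and 0.11, and between 0.0023 and 0.11 over all alternatives. The values of sens, ato and ey were 5.26, 15.5 and 47.7 FPKM (limma adjusted p = 0.132, 0.148 and 0.358).

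Heat shock genes gave 4 lower of 15 (9 adjusted over the list alone; limma camera adjusted p = 2.7e-05, adjusted p = 0.164 with an estimated correlation). Hemocyte markers gave 1 higher and 1 lower of 19, also when adjusted over the list alone (limma camera adjusted p = 0.00381, adjusted p = 0.548 with an estimated correlation). The lower one was BM-40-SPARC, at 34.7 FPKM (limma adjusted p = 0.000361). Antennal markers gave 2 higher and 2 lower of 13 (2 and 3 adjusted over the list alone; camera adjusted p = 0.285), with Dll at 4.37 ± 2.68 FPKM (11.1-fold, limma adjusted p = 0.000851). Immune peptides gave 2 higher of 17 (2 adjusted over the list alone; limma camera adjusted p = 0.0721). JNK and stress genes gave 2 higher and 3 lower of 22, also when adjusted over the list alone (limma camera adjusted p = 0.685, downwards, with a median and a mean above 0). Apoptosis genes gave 1 higher and 3 lower of 16 (2 and 3 adjusted over the list alone; limma camera adjusted p = 0.748, downwards, with a median and a mean above 0). The apoptosis gene that rose was grim, an activator of cell death, from 2.12 to 6.13 FPKM (limma adjusted p = 0.00262). Glia markers gave 2 higher and 2 lower of 15, also when adjusted over the list alone (limma camera adjusted p = 0.617). Muscle markers gave 1 higher and 2 lower of 17 (2 and 2 adjusted over the list alone; limma camera adjusted p = 0.0992). Optic lobe and brain markers gave 2 lower of 13 (1 higher and 3 lower adjusted over the list alone; limma camera adjusted p = 0.0721). Fat body markers gave 3 lower of 15 (3 adjusted over the list alone; limma camera adjusted p = 0.444, downwards, with a median and a mean above 0). Dosage and sex markers gave 1 lower of 10 (1 adjusted over the list alone; limma camera adjusted p = 0.297).

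For Trichoplax Yap S81A, 1122 genes were called, 561 higher and 561 lower, and 441 (169 higher and 272 lower) changed at least 2-fold. Without Trichoplax Yap S81A replicate 3 the count was 745, with array weights 2156 and with the within-group axis as a covariate 2077.

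The comparisons with the control shared many of their genes. Monosiga Yap-TBD, Yki S168A and Trichoplax Yap S81A had 691 called genes in common, of which 303 were higher and 384 lower in all 3. For Yki S168A and Trichoplax Yap S81A, 364 higher and 412 lower calls were shared, against 30.4 and 36.6 for independent lists of those sizes. The corresponding counts were 381 and 492 for Monosiga Yap-TBD and Yki S168A (62.9 and 72 if independent) and 418 and 494 for Monosiga Yap-TBD and Trichoplax Yap S81A (70.7 and 67.2 if independent). Simulated unchanged groups against the same controls shared at most 1 call in 100 simulations. That count was low by design, because unchanged groups give almost no calls. It does not measure what shared controls add to lists of real calls, and the simulated noise was independent between genes. The covariance of the log2 fold changes was 0.26 for Yki S168A and Trichoplax Yap S81A and 0.28 for Monosiga Yap-TBD and Yki S168A. It was 0.33 for Monosiga Yap-TBD and Trichoplax Yap S81A. Simulated unchanged groups with shared controls gave 0.07, with the spread of each gene pooled over all 5 groups. The correlations across genes were 0.75, 0.69 and 0.72 against 0.50 in these simulations. The 3 control libraries could not be split between the comparisons, so part of the excess can come from the shared controls. The calls of Monosiga Yap were shared with Yki S168A in 20 cases, 11 higher and 9 lower (1.14 and 0.587 if independent). They were shared with Monosiga Yap-TBD in 12 higher and 7 lower cases (2.65 and 1.08 if independent) and with Trichoplax Yap S81A in 11 and 7 (1.28 and 0.548 if independent). The covariances of Monosiga Yap with these constructs, 0.09, 0.08 and 0.09, were close to the simulated 0.07, which rests on the pooled spread. The correlations were 0.41, 0.27 and 0.37. They cannot be judged against the simulated 0.50, which holds for pairs of groups without any change. Changes in a single construct of a pair lower the correlation.

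Adding the TEAD-binding domain to Monosiga Yap was examined directly, with no control libraries in the contrast. The RNA levels of Monosiga Yap, Monosiga Yap-TBD and Trichoplax Yap S81A themselves were not among the values. A difference in construct level or stock between the Monosiga groups therefore cannot be told apart from an effect of the domain. Several Yki targets and many replication genes were higher with the domain, and many neuronal and photoreceptor genes lower. The difference in ex was 3.17-fold (309 ± 36.2 against 97.5 ± 14.2 FPKM; SD, n = 3; limma adjusted p = 2.07e-06). It was 2.98-fold in CycE (limma adjusted p = 3.89e-05), in vn 7.67-fold (adjusted p = 1.77e-06), in kibra 3.57-fold (adjusted p = 5.1e-06) and in dally 2.35-fold (adjusted p = 4.2e-05). The level of elav was 0.31 of that with Monosiga Yap (limma adjusted p = 1.73e-05). The level of inaC was 3.99 against 51.3 FPKM and ana at 0.60 against 19.0 FPKM (limma adjusted p = 1.59e-08 and 1.67e-07). Cpr97Eb was 239-fold, Cpr12A 120-fold and Cyp18a1 108-fold higher with the domain.

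Yki targets were higher in 10 of 15 cases (10 adjusted over the list alone; limma camera adjusted p = 1.51e-06, adjusted p = 0.165 with an estimated correlation). DNA replication genes were higher in 38 of 48 (39 adjusted over the list alone; limma camera adjusted p = 5.41e-17, adjusted p = 0.243 with an estimated correlation), and ribosome biogenesis genes in 26 of 35 (28 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.7e-08, adjusted p = 0.369 with an estimated correlation). Mitosis genes were higher in 19 cases and lower in 1 (20 and 1 adjusted over the list alone; limma camera adjusted p = 8.59e-06, adjusted p = 0.446 with an estimated correlation). Neuronal genes were lower in 22 of 40 cases (22 adjusted over the list alone; limma camera adjusted p = 4.91e-09, adjusted p = 0.243 with an estimated correlation). Photoreceptor genes were lower in 19 and higher in 4 (21 and 5 adjusted over the list alone; limma camera adjusted p = 8.69e-07, adjusted p = 0.165 with an estimated correlation), and cone and pigment cell genes lower in 10 and higher in 1 (10 and 3 adjusted over the list alone; camera adjusted p = 0.000688, adjusted p = 0.302 with an estimated correlation). Of 15 heat shock genes, 7 were lower and 2, Hsp60 and Hsc70-4, higher, the same counts adjusted over the list alone (limma camera adjusted p = 0.0053 for lower, adjusted p = 0.302 with an estimated correlation). The calls of Hsp60 (1.44-fold, limma adjusted p = 0.0206) and Hsc70-4 (1.37-fold, adjusted p = 0.0222) each ended without Monosiga Yap replicate 2 or Monosiga Yap-TBD replicate 2. That of Hsp60 also ended without Monosiga Yap replicate 1 and that of Hsc70-4 without Monosiga Yap-TBD replicate 1. Over all alternatives limma adjusted p ranged from 0.000579 to 0.0983 for Hsp60 and from 0.00421 to 0.115 for Hsc70-4. Of 19 hemocyte markers, 3 were lower, also when adjusted over the list alone (limma camera adjusted p = 0.0148, adjusted p = 0.446 with an estimated correlation). So were 4 of 16 Notch targets (4 adjusted over the list alone; limma camera adjusted p = 0.0218, adjusted p = 0.454 with an estimated correlation) and 4 of 13 retinal determination genes (4 adjusted over the list alone; camera adjusted p = 0.0334, adjusted p = 0.439 with an estimated correlation). In all 2442 genes were called, 1315 higher and 1127 lower, 898 with at least a 2-fold change. The level of th was 1.21-fold higher (limma adjusted p = 0.0162), a call that ended without Monosiga Yap replicate 2 or Monosiga Yap-TBD replicate 3 and with either normalization between libraries. Its limma adjusted p was between 0.0234 and 0.0678 over the single libraries left out and between 0.0064 and 0.282 over all alternatives. The level of wg was 2.90-fold higher (limma adjusted p = 0.0174), a call that ended without Monosiga Yap replicate 2 or Monosiga Yap-TBD replicate 2. For it, limma adjusted p ranged from 0.0125 to 0.0867, and from 0.0061 to 0.0924 over all alternatives.

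Trichoplax Yap S81A and Yki S168A, the proteins with a serine substitution, differed in few genes. Among genes higher with the Trichoplax protein, Ast-C was at 177 ± 78.7 against 1.37 ± 0.59 FPKM (SD, n = 3; limma adjusted p = 3.9e-07). Cpr97Eb was at 53.9 against 2.83 FPKM (limma adjusted p = 4.77e-05) and unc-13-4A, of a family that primes vesicle release, at 7.83 against 0.27 (adjusted p = 1.6e-06). NetA, the axon guidance gene netrin A, was at 24.6 ± 2.81 against 3.35 ± 0.81 (limma adjusted p = 7.77e-06). Rh5 was 5.84-fold higher (limma adjusted p = 8.6e-05). Lower with the Trichoplax protein were yki (75.3 against 603 FPKM, limma adjusted p = 4.51e-07), ana (1.24 against 16.8 FPKM, adjusted p = 7.77e-06), mthl8 (0.01 against 5.64, adjusted p = 5.29e-07) and brk, a repressor of Dpp target genes (21.9 against 54.4 FPKM, adjusted p = 0.00269). The call of brk ended without the 4 libraries lowest on the within-group axis (limma adjusted p = 0.0988, the highest of a range that begins at 2.61e-05).

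No difference between these proteins was called in ex (log2 fold change -0.11 ± 0.15 SE, limma adjusted p = 0.942), CycE (0.34 ± 0.18, adjusted p = 0.903), wg (0.85 ± 0.36, adjusted p = 0.789), hth (-0.47 ± 0.20, adjusted p = 0.787), th (-0.04 ± 0.08, adjusted p = 0.964) or elav (0.05 ± 0.18, adjusted p = 0.982). Camera called immune peptides higher with the Trichoplax protein, where limma called 1 of 17 (3 adjusted over the list alone; limma camera adjusted p = 1.51e-07, adjusted p = 0.408 with an estimated correlation). Camera also called DNA replication genes higher (limma adjusted p = 0.001, adjusted p = 0.915 with an estimated correlation). It called ribosome biogenesis (adjusted p = 4.99e-05, adjusted p = 0.808 with an estimated correlation), antennal (adjusted p = 0.001, adjusted p = 0.256 with an estimated correlation) and heat shock genes (adjusted p = 0.00492, adjusted p = 0.454 with an estimated correlation) lower, each without a member called by limma. The count was 47 (32 higher and 15 lower), beside 539 genes at an unadjusted limma p under 0.05. It was 29 and 30 without Yki S168A replicate 2 or 3, 23 without the 4 libraries lowest on the within-group axis, 28 with only the groups compared in the fit, 83 with the within-group axis as a covariate and 699 with array weights.

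**Figure D4:**
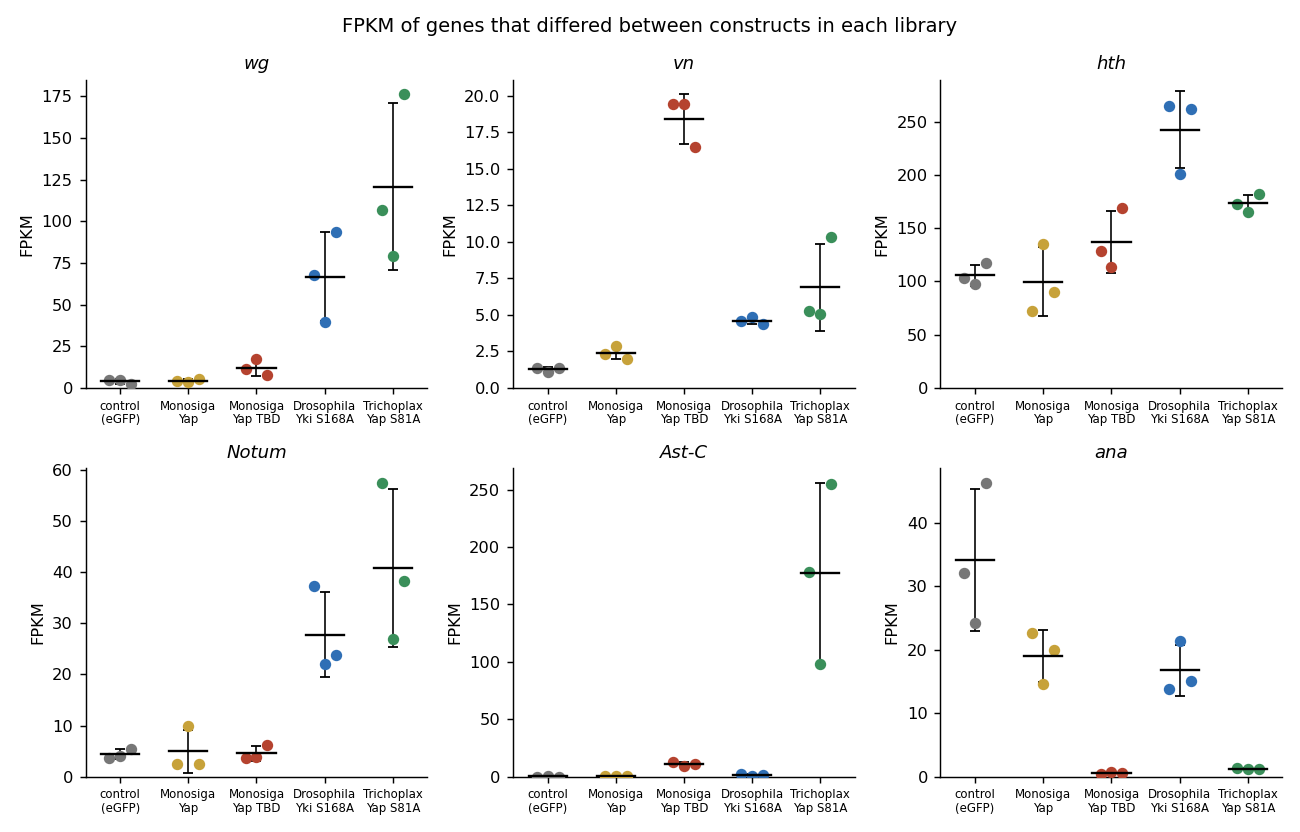
FPKM of wg, vn, hth, Notum, Ast-C and ana in each of the 15 libraries (points), with the mean and SD of each group (bars and lines). Ast-C is at 177 FPKM on average with Trichoplax Yap S81A against 1.37 with Yki S168A.

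Monosiga Yap-TBD differed more from the animal proteins with a serine substitution. Against Yki S168A, 657 genes were called (312 higher and 345 lower) and against Trichoplax Yap S81A 582 (275 higher and 307 lower, but 373 and 262 with each library centred on its median). The genes of this paragraph and the next were chosen after their values were seen. The gene hh fell with Monosiga Yap-TBD to 13.5 FPKM from 21.8 in the control (limma adjusted p = 0.0317) and rose with the other two. The difference in its log2 fold change was -1.61 from Yki S168A (limma adjusted p = 0.000146) and -1.91 from Trichoplax Yap S81A (adjusted p = 3.57e-05). Ppn fell to 49.8 FPKM (limma adjusted p = 0.00252), with differences of -1.84 and -1.61 (adjusted p = 2.21e-05 and 7.6e-05). Relative to Yki S168A, photoreceptor genes were lower in 9 of 36 cases and higher in 1 (13 and 2 adjusted over the list alone; limma camera adjusted p = 0.00012, adjusted p = 0.304 with an estimated correlation). Neuronal genes were lower in 8 and higher in 1 (11 and 1 adjusted over the list alone; limma camera adjusted p = 8.01e-05, adjusted p = 0.552 with an estimated correlation). Antennal markers were lower in 6 of 13 (7 adjusted over the list alone; limma camera adjusted p = 8.01e-05, adjusted p = 0.089 with an estimated correlation). Cone and pigment cell genes were lower in 6 and higher in 1 of 16 (9 and 1 adjusted over the list alone; limma camera adjusted p = 8.59e-05, adjusted p = 0.341 with an estimated correlation), and retinal determination genes were lower in 5 of 13 (6 adjusted over the list alone; camera adjusted p = 0.00535, adjusted p = 0.552 with an estimated correlation). JNK and stress genes were higher in 3 and lower in 1 of 22 (5 and 1 adjusted over the list alone; limma camera adjusted p = 0.0389, adjusted p = 0.795 with an estimated correlation). DNA replication genes were higher in 2 (limma camera adjusted p = 0.0389, adjusted p = 0.875 with an estimated correlation), and ribosome biogenesis genes were higher as a list (camera adjusted p = 0.00988, adjusted p = 0.875 with an estimated correlation). Yki targets gave 3 higher and 3 lower of 15, also when adjusted over the list alone (limma camera adjusted p = 0.704). Without Monosiga Yap-TBD replicate 1 or 2 or Yki S168A replicate 2, the count of 657 was 397, 378 or 363, without the 4 libraries lowest on the within-group axis 397, with array weights 3460 and with the within-group axis as a covariate 1419.

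Relative to Trichoplax Yap S81A, neuronal genes were lower in 10 of 40 cases (14 lower and 1 higher adjusted over the list alone; limma camera adjusted p = 6.83e-07, adjusted p = 0.414 with an estimated correlation). Photoreceptor genes were lower in 8 of 36 (11 adjusted over the list alone; limma camera adjusted p = 4.86e-06, adjusted p = 0.286 with an estimated correlation) and cone and pigment cell genes in 7 of 16, with 1 higher (also when adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.414 with an estimated correlation). Ribosome biogenesis genes were higher as a list (limma camera adjusted p = 2.47e-08, adjusted p = 0.452 with an estimated correlation), as were JNK and stress genes, 2 of them called (camera adjusted p = 0.0107, adjusted p = 0.452 with an estimated correlation). Yki targets again gave 3 higher and 3 lower, also when adjusted over the list alone (limma camera adjusted p = 0.565). The sulfotransferase gene pip stood at 15.1 FPKM with Monosiga Yap-TBD, 102 with Trichoplax Yap S81A and 32.8 in the control, a difference in log2 fold change of -2.69 (limma adjusted p = 1.9e-05). Without Monosiga Yap-TBD replicate 1 or 2 the count of 582 was 317 or 327, without the 4 libraries lowest on the within-group axis 368, with array weights 1746 and with the within-group axis as a covariate 1102.

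Against Monosiga Yap instead of the control, both animal proteins gave similar counts: 1075 genes for Yki S168A (476 higher and 599 lower) and 1172 for Trichoplax Yap S81A (553 higher and 619 lower). Without Monosiga Yap replicate 3 more were higher than lower, 791 and 565 for Yki S168A and 967 and 621 for Trichoplax Yap S81A. DNA replication genes were higher in 29 and 35 of 48 cases (35 and 40 adjusted over the list alone; limma camera adjusted p = 1.09e-21 and 1.06e-24, adjusted p = 0.189 and 0.17 with an estimated correlation). Mitosis genes were higher in 20 and 19 of 54 (24 and 33 adjusted over the list alone; camera adjusted p = 1.55e-11 and 3.54e-12, adjusted p = 0.324 and 0.266 with an estimated correlation) and Yki targets in 8 and 8 of 15 (9 and 8 adjusted over the list alone; camera adjusted p = 2.9e-08 and 1.81e-07, adjusted p = 0.0845 and 0.17 with an estimated correlation). Neuronal genes were lower in 14 and 13 of 40 cases and higher in 2 and 2 (limma camera adjusted p = 1.46e-07 and 4.16e-06, adjusted p = 0.295 and 0.266 with an estimated correlation). Photoreceptor genes were lower in 15 and 15 of 36 and higher in 4 and 6 (limma camera adjusted p = 0.000172 and 0.00129, adjusted p = 0.189 and 0.253 with an estimated correlation), and Notch targets lower in 5 and 5 of 16 (camera adjusted p = 4.29e-05 and 8.86e-05, adjusted p = 0.324 and 0.266 with an estimated correlation). Ribosome biogenesis genes were higher in 10 and 2 of 35 (limma camera adjusted p = 2.9e-08 and 0.00243, adjusted p = 0.389 and 0.667 with an estimated correlation). Optic lobe markers were lower in 3 and 3 of 13 (limma camera adjusted p = 0.00122 and 0.0114, adjusted p = 0.0845 and 0.17 with an estimated correlation), and heat shock genes lower (camera adjusted p = 0.0197 and 0.000147, adjusted p = 0.389 and 0.196 with an estimated correlation). Camera also called hemocyte markers, immune peptides and muscle markers for Yki S168A (each limma adjusted p = 0.0197, adjusted p = 0.479, 0.52 and 0.479 with an estimated correlation) and muscle markers for Trichoplax Yap S81A (adjusted p = 0.0255, adjusted p = 0.667 with an estimated correlation). Without Yki S168A replicate 3 the count of 1075 was 670, without the 4 libraries lowest on the within-group axis 509, with only the groups compared in the fit 479, with the axis as a covariate 1996 and with array weights 2503. The count of 1172 became 653, 604, 2319 and 1998 under the last 4 of these.

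The table of comparisons with the control that the authors deposited was set beside these calls. With the authors' own adjusted p under 0.05, not from limma, it called 1711 genes for Monosiga Yap-TBD, 1076 for Yki S168A, 1020 for Trichoplax Yap S81A and 206 for Monosiga Yap (93 higher and 113 lower). Of these, 1545, 909, 802 and 67 passed the filter on FPKM and were tested here, so that most of the authors' calls for Monosiga Yap were not. Among the tested ones the test used here called 1324, 632, 591 and 11, each in the same direction. It called a further 940, 468, 530 and 19 genes that the authors' table did not. Of these, 57, 25, 41 and 4 had a log ratio of 0 and a p-value of 1 in that table, and the labels do not state whether the authors tested them. The correlations across genes between the fold changes were 0.84, 0.76, 0.78 and 0.68.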

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

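The tests of this part, apart from the splits of the libraries, were chosen after seeing the result. In 3 pairs of comparisons some genes were called in opposite directions. Against the control, these were 3 for Monosiga Yap and Monosiga Yap-TBD: CG34038 and CG13044, higher with Monosiga Yap, and GstD3, lower. For Monosiga Yap-TBD and Yki S168A they were 9: CG31955, CG1850, CG34350, CG11073, GstD3, hh, CG31076, Ppn and CG32521. For Monosiga Yap-TBD and Trichoplax Yap S81A these were also 9: B4, CG14470, CG1850, CG10051, RhoGEF4, pip, hh, Ppn and CG32521. The genes hh, Ppn, CG1850 and CG32521 stand in both sets. The largest such difference in log2 fold change from Yki S168A was that of CG11073 (2.93, limma adjusted p = 2.32e-08), at 234.9 FPKM with Monosiga Yap-TBD, 30.2 with Yki S168A and 43.1 in the control. The cause was not tested.

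Lower photoreceptor and neuronal genes may reflect fewer neurons in the libraries, all lost alike, in which case these genes would fall by as much as elav. With Monosiga Yap-TBD, 10 of 39 lower members also fell relative to elav by a limma test of the log2 ratio (sev, salr, inaC, chp, salm, retn, nrv3, ru, svp and n-syb), with Trichoplax Yap S81A 6 of 23 (sev, salr, salm, inaC, svp and ru) and with Yki S168A 4 of 27 (sev, salm, salr and ru). The test cannot tell, because these are among the genes with the largest falls, most lower members did not fall relative to elav, elav overlaps another gene, and sev and ru are also expressed outside cells that hold elav. A loss of all neurons alike, neurons that are younger or less mature, and a different mixture of neuron types all remain possible. Single-cell sequencing or staining for elav beside salm in the same discs could tell these apart.

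The calls of Monosiga Yap may be a weak form of the response to the other constructs, or may reflect a difference between the control stock and all construct stocks. Of its 30 calls, 20 moved the same way with the 3 other constructs, and 16 were called the same way in all 4. Over the 20, the median ratio of the mean log2 fold change with the others to that with Monosiga Yap was 0.839 (0.757 to 1.29, 95% of 2000 bootstrap draws). Because these genes were selected by their change with Monosiga Yap and for moving alike, and share the control libraries, the ratio cannot tell the explanations apart, and both remain open. Of the 30 calls, 11 differ from each of the 3 other constructs: ex, CG11029 and CG15449 changed less with Monosiga Yap, as a weak form predicts, and 8 changed more (Cda5, Gld, CG16820, CG8172, CG34038, CG13044, CG14681 and CG32816), which neither explanation predicts. The pigment gene y stood at 0.04, 0.17 and 0 FPKM in the control libraries against 5.18, 4.19 and 2.13 with Monosiga Yap (CG32816 spans it). Its log2 fold change of 2.12 there stands against 0.87 with Monosiga Yap-TBD, 0.69 with Yki S168A and 1.18 with Trichoplax Yap S81A. The difference from Monosiga Yap was called for 2 of these 3 constructs. As 1 gene near the floor, y cannot tell whether all construct stocks share an allele difference from the control stock.

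Higher Dll with Yki S168A and Trichoplax Yap S81A might come from antennal tissue carried over in the dissection, which would raise other antennal genes too. The test took 8 further antennal genes with a mean control FPKM under 5. In each of these groups 1 of them, al, lay above every control library in all 3 libraries. It did so with Monosiga Yap-TBD as well, where Dll was not called. B-H1, at 14.8 FPKM in the control and also on the photoreceptor list, was not among the 8. It was called higher with Yki S168A (31.8 FPKM, limma adjusted p = 0.000871) and Trichoplax Yap S81A (23.25 FPKM, limma adjusted p = 0.0226). The antennal list member dan was called lower in both, and oc lower with Trichoplax Yap S81A. The test cannot tell. Yki S168A replicate 3 alone had al at 5.11, Lim1 at 1.38, disco at 1.5 and disco-r at 2.4 FPKM, while Dll was 8.56, 5.07 and 9.47 FPKM in replicates 1, 2 and 3. Staining of whole discs for Dll would answer this.

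Regrouping the 6 libraries of each comparison into 3 and 3 gives 10 splits, in 1 of which, the real one, the count of called genes was reached in each of the 10 comparisons. The splits are too few for a share under 0.05. The real counts, 30 to 2442, are those given in the results for each comparison. The highest count of another split was 0 or 1 in each. Every other split mixes libraries of both groups, so a real difference widens the spread and shrinks the difference in means. Its low count was therefore built in and does not measure how many calls arise by chance.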

How the results depend on the processing

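The 458 values of named genes were computed 8652 times under the alternatives. Of these, 8042 kept their call or lack of one, 590 lost a call and 20 gained one. A change of sign with a call before or after occurred in 0. The size of the change was not compared, and a change of sign without a call counted as kept. Counts of called genes are given below where they moved by more than 1.5 times, in the order Monosiga Yap (M), Monosiga Yap-TBD (MT), Yki S168A (DS) and Trichoplax Yap S81A (TS), each against the control (C), then the other contrasts. With array weights they were M 79, MT 4014, DS 3033, TS 2156, TS-DS 699, MT-DS 3460, MT-TS 1746, DS-M 2503 and TS-M 1998. With the within-group axis as a covariate, chosen after seeing the data and circular because it is made from the residuals, they were M 58, MT 3458, DS 1993, TS 2077, TS-DS 83, MT-DS 1419, MT-TS 1102, DS-M 1996 and TS-M 2319. Without the libraries of lowest roX level (also chosen after seeing the data) M gave 17, and without the 4 libraries lowest on the axis TS-DS gave 23, MT-DS 397, MT-TS 368, DS-M 509 and TS-M 653. With only the groups compared in the fit, M gave 16, TS-DS 28, DS-M 479 and TS-M 604. With a change of at least 2-fold required, MT gave 871, DS 382, TS 441, MT-M 898, MT-DS 294, MT-TS 270, DS-M 343 and TS-M 446.

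Leaving out 1 library gave counts of 16 (without Monosiga Yap replicate 1) to 21 (without control replicate 3) for M, 1621 to 2068 for MT, 723 (without control replicate 2) to 831 for DS, 745 (without Trichoplax Yap S81A replicate 3) to 890 for TS, 1697 to 2801 for MT-M and 29 (without Yki S168A replicate 2) to 37 for TS-DS. It gave 363 (without Yki S168A replicate 2) to 651 for MT-DS, 317 (without Monosiga Yap-TBD replicate 1) to 447 for MT-TS, 670 (without Yki S168A replicate 3) to 1356 for DS-M and 831 to 1588 for TS-M. The other libraries that moved a count by more than 1.5 times are named with their values in the report.

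The share of higher genes among the calls moved by more than 10 percentage points in some cases. It was 68.1% for TS-DS and 47.3% for MT-TS, but 56.4% and 58.7% with each library centred on its median. It went from 44.3% to 58.3% for DS-M and from 47.2% to 60.9% for TS-M without Monosiga Yap replicate 3, and from 70% to 88.2% for M without control replicate 1.

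The list tests depended on the inter-gene correlation. With the preset value camera called 2 lists for M, 10 for MT, 10 for DS, 9 for TS, 11 for MT-M, 5 for TS-DS, 8 for MT-DS, 5 for MT-TS, 12 for DS-M and 10 for TS-M, and with an estimated correlation 0 in each. Without a filter it called 4 for M and 9 for MT-TS.

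With a replicate block the counts were M 25, MT 2148, DS 1002, TS 1039, MT-M 2299, TS-DS 39, MT-DS 541, MT-TS 540, DS-M 971 and TS-M 1082. The numbers do not pair the libraries: 7 of 30 pairs with the same number had correlated deviations (over 0.1), and as a hint 3 of 15 libraries were closest to their own number.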

Other observations

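The tests and groups of genes in this part were chosen after seeing the results. Genes of mitochondrial ribosomal proteins were higher with Monosiga Yap-TBD. Of 71 tested, 32 were called higher against the control by limma, with a median log2 fold change of 0.56 and 71 above 0 (69 with quantile normalization, where 37 were called, and 45 called with each library centred on its median). Camera gave p = 1.77e-12, and 0.205 with an estimated correlation. Against Monosiga Yap, 46 were higher (camera p = 4.49e-14, and 0.178 with an estimated correlation). With Yki S168A and Trichoplax Yap S81A against the control the median was 0.17 and 0.26, with 64 of 71 above 0 in each. There limma called 0 genes each (3 and 0 with each library centred on its median). Camera gave p = 0.00196 and 0.00026, and 0.566 and 0.499 with an estimated correlation. The direct contrasts of Monosiga Yap-TBD with these 2 constructs gave medians of 0.35 and 0.31 and called 2 genes each (camera p = 1.51e-12 and 1.43e-11, and 0.204 and 0.224 with an estimated correlation). Of the other families tested with Monosiga Yap-TBD against the control, limma called 0 higher and 3 lower of 80 cytoplasmic ribosomal protein genes (median -0.12, camera p = 0.00323, and 0.627 with an estimated correlation). These were 2 and 7 with quantile normalization (median -0.04) and 0 and 2 with each library centred on its median (-0.16). By limma, 5 were higher and 4 lower of 29 cytochrome P450 genes (median -0.19), 6 and 5 of 36 cuticle protein genes (-0.28) and 4 and 2 of 171 small RNA genes (0.55). Camera of limma with the preset correlation gave p = 0.612, 0.823 and 0.218 for these families.

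The libraries differed within groups along a main axis that held 28.3% of the variance of deviations from the group means. Of the 100 genes with the largest weights on it, 33 were small RNA genes, against 93 of the 6571 genes in the axis. The level of roX1, a male-specific RNA, was 12.3 FPKM in Trichoplax Yap S81A replicate 2 and 18.7 in Monosiga Yap replicate 3, against 196.8 in Monosiga Yap replicate 1.

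In the deposited table of comparisons, the log ratio was 0 and the p-value 1 for 257 genes for Monosiga Yap, 270 for Monosiga Yap-TBD, 262 for Yki S168A and 274 for Trichoplax Yap S81A. Of these genes the test on FPKM values called 4, 57, 25 and 41. Examples are y for Monosiga Yap, Tm1 for Monosiga Yap-TBD and hth for Yki S168A. Ts and Mcm10 are among them for Monosiga Yap-TBD, Yki S168A and Trichoplax Yap S81A alike.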
